A study of Mus musculus with 9 samples.

How the data were processed

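Whole flash-frozen medulloblastomas of SmoM2 mice, 3 labelled Cdk6+/+ and 6 labelled Cdk6-/-, were extracted with Trizol, and 1 microgram of total RNA went into an Illumina TruSeq kit, per the labels' protocols. Illumina HiSeq sequencing gave 50-base single-end reads, at least 37 x 1e6 per sample, per the series' design text. The submitters' processing notes name FastQC, Trimmomatic, HISAT2 and DESeq2 without versions and the genome build GRCm38.p6. The counting tool, its handling of strand and of reads with several alignments, and the annotation release are not given in the sources used here.

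The authors deposited a table of whole-number counts per gene, unnormalized, with 1 column per tumour and with the position, strand and exon length of each gene per the file headers. They also deposited a table of their DESeq2 result. Its log2 fold changes and standard errors, its p-values and adjusted p-values, and a score that equals the negative log2 of the p-value are as the authors deposited them, and the score was not used. Design formula and filter of that fit are not given in the sources used here.

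The count table has 47593 rows. A spreadsheet had altered 25 gene names to dates, and all 25 were restored by matching the row's position. The names were matched to GENCODE M21, the annotation used here for gene classes and sequences: 95.1% matched, 85.6% of these with identical start and end and 99.96% with overlapping positions. Coordinates are those of the deposited table, and 8 rows span several chromosomes. Library totals ran from 21.4 to 56.8 x 1e6 counts. A gene without a count in a group could be present at up to 3 counts over that group, 0.0221 CPM in Cdk6+/+ and 0.0197 CPM in Cdk6-/-. Intervals of count ratios and this limit cover counting error only. Chi-square tests of the counts of each pair of libraries within a group gave 34.0 or more per degree of freedom, so no pair of columns held the same library.

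Groups were taken from the description and genotype in the labels. Genes were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3), which kept 18356 and removed 29237, scaled by TMM and tested with edgeR's quasi-likelihood F test (robust, two-sided, genotype only), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are counts per 1e6 counts of the TMM-scaled library. Log2 fold changes are Cdk6-/- minus Cdk6+/+ and standard errors are derived from the test statistic. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a correlation of 0.01, again with a correlation estimated per list, and with fry, adjusted over the 27 lists. The lists cover cyclins, CDKs and inhibitors, E2F targets, G2/M, the Hedgehog pathway, ribosomal proteins, the unfolded protein response, cholesterol synthesis, oxysterols, p53 targets, interferon response, the respiratory chain, glycolysis, granule neuron progenitors and differentiation, markers of 10 other cell types, immediate early genes, mitochondrially encoded genes and sex-linked genes. Lists, tests and the rule below were set before the data were examined.

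Genes named in the text are Cdk6, then, among genes at an adjusted p under 0.05 with a mean of at least 1 CPM and every Cdk6-/- library on the same side of every Cdk6+/+ library, the 10 largest increases and the 10 largest decreases. Predicted genes, Rik clones and pseudogenes were passed over there, 219 of 516. Next come the 4 members of each pathway or lineage list, and the 2 of each cell type or quality list, with the smallest p, printed only where needed. Of all tested genes, 2852 (15.5%) had groups fully apart, where chance gives 2.38%. Against a group with 1 to 3 counts, ratios of summed counts are given with exact binomial (Clopper-Pearson) intervals.

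Shared sequence is the percent of a gene's 50-base sequences, over all its GENCODE M21 transcripts, that occur exactly in another annotated gene. Exons on opposite strands and genes inside other genes were taken from the same annotation. Enrichments used Fisher's exact test against all tested genes. Matched random lists, 10000 per test, were drawn from 5 bins per matching variable. Calculations outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

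The steps were tested on simulated data made from the real means, library sizes and fitted dispersions with 200 genes changed. At the fitted dispersion the test recovered 0% of 100 genes changed 2-fold and 20% of 100 genes changed 4-fold (17903 genes tested). With dispersions of at most 0.05 it recovered 77% and 100% (17945 genes tested). A shifted list was found and 0 of 26 other lists were called. The simulation drew genes independently, whereas the estimated correlation in the data was 0.843 for the ribosomal list. It therefore does not check the list test where the genes of a list vary together. The common biological coefficient of variation of the 9 libraries was 0.542, and 0.348 without Cdk6-/- tumours 1 and 5.

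Alternatives set in advance were DESeq2 1.42.0, limma-voom, other normalizations and filters, a fold change minimum, the replicate number as a block, each library left out in turn, a Y-linked covariate, X and Y genes left out, an estimated list correlation and other flank windows. Leaving out Cdk6-/- tumours 1 and 5 together, thinning the counts to the smallest library and restricting to genes with under 10% shared sequence were added after the data were seen.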

Results

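RNA was sequenced from 9 whole medulloblastomas of C57BL/6J mice, tumours of the cerebellum that arise when an activated form of Smoothened (SmoM2), the signal transducer of the Hedgehog pathway, is switched on by Cre recombinase in Math1 (Atoh1) expressing granule neuron progenitors. The labels gave 3 tumours as Cdk6+/+ and 6 as Cdk6-/-. Cdk6 is a cyclin D dependent kinase that phosphorylates the retinoblastoma protein, and the comparison asked how tumours with the gene deleted differ from tumours with it intact. The deposited counts, in units of 1e6, summed to 56.8, 39.4 and 39.7 in Cdk6+/+ tumours 1 to 3 and to 21.4, 26.3, 34.5, 22.6, 24.7 and 23.0 in Cdk6-/- tumours 1 to 6. Every Cdk6+/+ library was therefore deeper than every Cdk6-/- library. The tumours are separate samples by label, and the p-values of single genes below measure the spread between them. Fisher's exact tests take genes as independent units. Camera with a preset correlation of 0.01 compares genes and takes those of a list as nearly independent. Those p-values do not measure the spread between tumours.

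The libraries also differed in the sex-linked genes. Xist, expressed from the inactive X chromosome, was between 1583 and 2087 CPM (counts per 1e6 counts) in the 3 Cdk6+/+ libraries, 131 in the library of Cdk6-/- tumour 1 and 1757 in that of tumour 6. In Cdk6-/- tumours 2, 3, 4 and 5 Xist was below 1 CPM, and the Y-linked gene Ddx3y was at 145, 57.6, 77.9 and 144 CPM. Ddx3y had no count in any Cdk6+/+ library. Sex by these genes was therefore partly confounded with the genotype labels.

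Cdk6 itself was not clearly lower in the libraries labelled Cdk6-/-. The gene (chromosome 5, 3341485 to 3531008, GRCm38) was counted at 562, 551 and 562 CPM in the Cdk6+/+ libraries and at 214, 562, 270, 464, 2.17 and 351 CPM in Cdk6-/- libraries 1 to 6. The group means were 558 ± 6.61 CPM (SD, n = 3) and 311 ± 197 CPM (SD, n = 6), a log2 fold change of -0.85 with a standard error (SE) of 0.93 that did not pass edgeR's quasi-likelihood test (adjusted p = 0.672). The labels do not name the deleted exon and the counts cover all exons of the gene, so transcript from outside the deleted part is included and these values do not check the genotype. The groups are called by their labels for that reason.

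Tumour 5 of the Cdk6-/- group had almost no transcripts of dividing cells. Mki67, a marker of proliferation, was at 0.398 CPM there and between 823 and 1056 CPM in the other 5 Cdk6-/- libraries, and Atoh1, the transcription factor of granule neuron progenitors, was at 0.0442 CPM against 51.8 to 197. The median gene of the G2/M list was at 0.716% of its median level in the other 5 libraries. Itpr1, an inositol trisphosphate receptor abundant in Purkinje cells, was at 5527 CPM in tumour 5 and at most 193 in the others, and Gabra6, a receptor subunit of mature granule neurons, was at 1054 CPM. Tumour 1 also had a high Gabra6 level, 931 CPM, against 2.51 to 38.7 CPM in tumours 2, 3, 4 and 6, but its median G2/M gene was at 102% of its level in those tumours. Results are given below with all 9 libraries and, where it changes them, without Cdk6-/- tumours 1 and 5, a choice made after the data were seen, as were the genes Mki67, Atoh1 and Gabra6 named here.

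**Figure D1:**
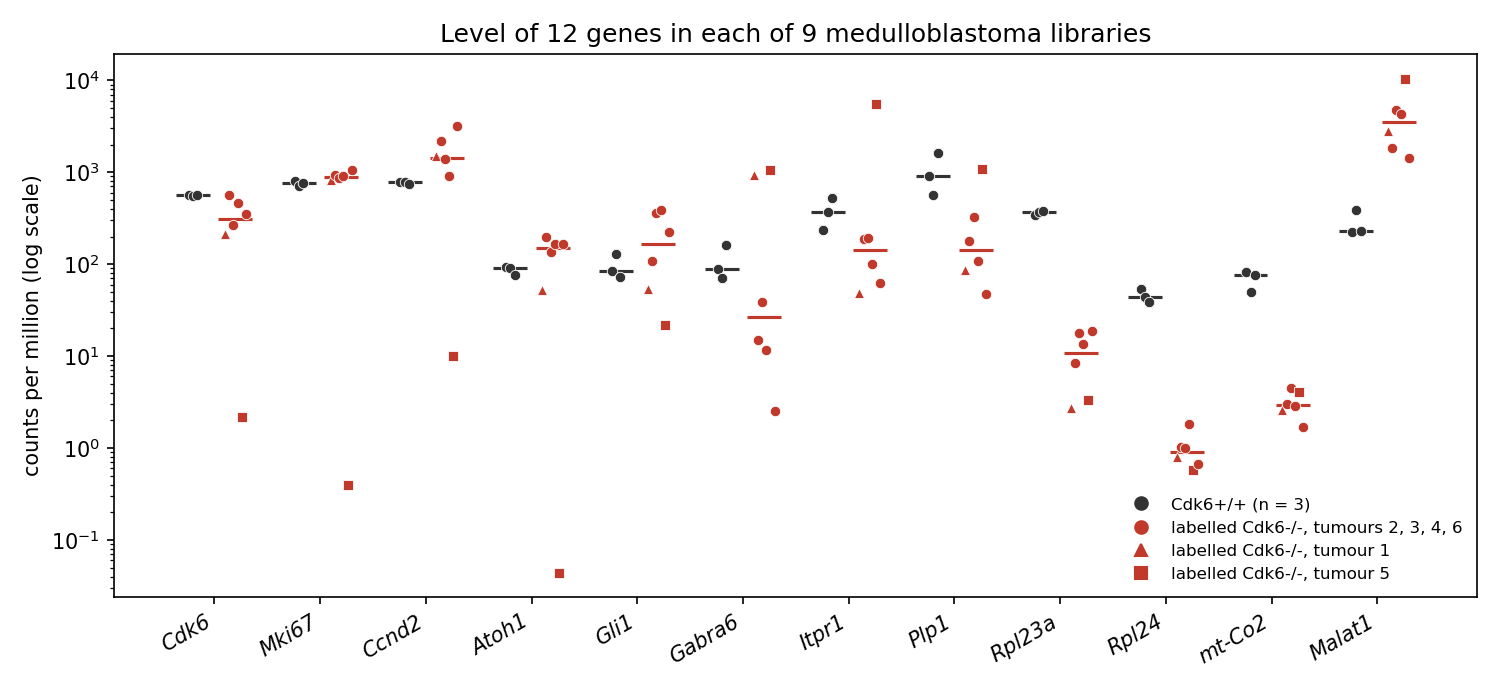
CPM on a log axis for 12 genes in each library, with black points for Cdk6+/+ tumours, red points for tumours labelled Cdk6-/-, triangles for tumour 1, squares for tumour 5 and bars at the group medians. Mki67 and Atoh1 fell out of the range of the other libraries in tumour 5, at 0.398 and 0.0442 CPM, while Rpl24 and mt-Co2 were lower in all 6 Cdk6-/- libraries than in all 3 Cdk6+/+ libraries.

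Across all genes, the libraries labelled Cdk6-/- had lower counts of ribosomal protein, globin and several mitochondrial genes and higher counts of unverified transcripts. Of 18356 genes tested, 953 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 507 higher and 446 lower in Cdk6-/-. Protein-coding genes made up 305 of these calls (71 higher, 234 lower) out of 14378 tested, or 2.12%. Of 766 tested pseudogenes 262 changed, 34.2% (Fisher's exact test, odds ratio 12.7, adjusted p = 1.08e-149). Of 740 tested transcripts of the TEC annotation class, which are unverified and mostly unspliced, 206 changed (odds ratio 8.71, adjusted p = 3.14e-96), 205 of them higher. Long noncoding genes changed about as often as the rest, 89 of 1588 (71 higher; odds ratio 1.09, Fisher's exact adjusted p = 0.442).

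By the same naming rule as for increases below, several lower genes reached near absence in the libraries labelled Cdk6-/-. Igf2bp1, an RNA-binding protein that stabilises mRNAs (chromosome 11, 95957163 to 96005940), had 5.51 ± 0.834 CPM (SD, n = 3) in Cdk6+/+ and 0.0165 ± 0.0403 (SD, n = 6) in Cdk6-/- libraries (log2 fold change -7.68, SE 0.84, adjusted p = 0.000977). Cox20, an assembly factor of cytochrome c oxidase (chromosome 1, 178319130 to 178322693), went from 3.20 to 0.0259 CPM (log2 fold change -6.75, SE 0.71), but 91.1% of its exon bases lie opposite exons of a gene on the other strand. Retnla, a secreted resistin-like protein, had 459 counts over the Cdk6+/+ libraries and 2 over the Cdk6-/- libraries, a ratio of 264 (exact 95% counting interval 72.7 to 2187). The adult beta globins Hbb-bt and Hbb-bs fell by 6.38 and 5.33 on the log2 scale, the ribosomal protein gene Rpl24 by 5.52 and the imprinted gene Peg12 by 5.19. Outside protein-coding genes, the 5S ribosomal RNA copy n-R5s194 had 1439 counts against 1 (ratio 1656, interval 297 to 65451), the mitochondrial proline tRNA mt-Tp had a log2 fold change of -5.48, and the clone transcript RP24-490A22.9 had -5.89.

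Among called genes with a mean of at least 1 CPM and every Cdk6-/- library above every Cdk6+/+ library, predicted genes and pseudogenes passed over, 1 of the 10 with the largest increases was protein-coding. Muc6, a secreted mucin (chromosome 7, 141633456 to 141655319), rose from 0.162 ± 0.222 CPM (SD, n = 3) to 9.99 ± 7.71 CPM (SD, n = 6), a log2 fold change of 5.93 (SE 1.28, adjusted p = 0.0268). Scarna9, a small nuclear RNA inside Cep295, rose from 0.129 to 4.23 CPM (log2 fold change 5.03), and Ppp2r2cos, an antisense gene inside Ppp2r2c, by a log2 fold change of 5.97. RP23-385F8.3, inside Prkcb, had 6.13, and RP23-378D16.5, inside Nav2 on the other strand, had 6.09. The remaining transcripts, RP23-52J10.4 (5.36), RP23-52J10.5 (4.71), RP23-52J10.3 (4.65) and 2 further clone transcripts, all lie inside Fam155a on its strand. Malat1, a nuclear long noncoding RNA chosen after its values were seen, was at 279 ± 93.2 CPM in Cdk6+/+ and 4259 ± 3298 CPM in Cdk6-/- libraries (SD; log2 fold change 3.93, SE 0.73, adjusted p = 0.0143). Whether counting used strand is not given in the sources used here, so reads of Ppp2r2cos, RP23-378D16.5 and Cox20 and of the genes opposite to them may be mixed.

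The count of changed genes depended on the libraries included and on the settings of the test. It was 2643 (1505 higher, 1138 lower) without Cdk6-/- tumours 1 and 5, 1506 without tumour 5, 525 (203 higher, 322 lower) without tumour 3, 221 (54 higher, 167 lower), 400 (128 and 272) and 207 (46 and 161) without Cdk6+/+ tumour 1, 2 or 3, 2894 (1957 higher, 937 lower) by DESeq2, 3735 by limma-voom, 563 (244 higher, 319 lower) among genes with at least 1 CPM in 3 libraries and 72 with the Y-linked level as a covariate. Of 14378 protein-coding genes, the 13225 with under 10% shared sequence gave 160 calls, 64 higher and 96 lower. Of 909 with over 10 to 50% shared sequence 12.4% were called, 5 higher and 108 lower. Of 244 with over 50% 13.1% were called, 2 higher and 30 lower. The share called was 1.00% with 0% shared sequence and 1.54% with over 0 to 10%, so decreases were concentrated in genes with shared sequence.

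Many cytosolic ribosomal protein genes were lower. Of 82 measured members 31 fell and 0 rose (51 fell adjusted over the list alone), all 82 had negative log2 fold changes, and the median was -1.55. Rpl24 was at 45.1 ± 7.73 CPM (SD, n = 3) and 0.981 ± 0.445 CPM (SD, n = 6), and Rpl23a at 364 and 10.7 CPM (log2 fold change -5.08, SE 0.58, adjusted p = 0.00129). Rpl36al and Rpl22l1 fell by 2.91 and 2.67. The list lay below other genes in camera with a preset correlation of 0.01 (adjusted p = 1.13e-30), and not with its own, adjusted p = 0.479 with an estimated correlation. Against no change, fry's directional test gave adjusted p = 0.0642, and 0.00383 without tumours 1 and 5. In Rpl24 51.8% and in Rpl23a 50.1% of the 50-base sequences also occur in another gene, and 59.7% of the exon bases of Rpl23a lie opposite another gene. The 14 ribosomal protein genes with under 10% shared sequence had a median of -1.43, and 3 of them fell. Without tumours 1 and 5 the median of the list was -1.22, 58 members fell and the list's camera adjusted p was 9.70e-28, with adjusted p = 0.379 with an estimated correlation.

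Nuclear genes of the mitochondrial respiratory chain were also lower, by less. Of 45 members 8 fell and 0 rose (15 fell adjusted over the list alone), with a median of -0.46. The examples with the smallest p were Cox7c (73.6 to 20.6 CPM, log2 fold change -1.84, SE 0.30, adjusted p = 0.00902), Cox5a (-1.22), Atp5h (-1.08) and Uqcrh (-1.13), subunits of cytochrome oxidase, ATP synthase and complex III. Camera gave adjusted p = 5.36e-08, adjusted p = 0.363 with an estimated correlation, and fry's directional test gave adjusted p = 0.0143. Of the 27 lists this one, the red cell list (adjusted p = 0.0143) and the interferon list (adjusted p = 0.0159) passed that test over all libraries. In the comparison without tumours 1 and 5, 16 respiratory chain genes fell (20 adjusted over the list alone). Of the 13 genes encoded by mitochondrial DNA 4 fell and 0 rose (5 fell adjusted over the list alone; median -0.29, camera adjusted p = 0.000337, adjusted p = 0.585 with an estimated correlation). Their median was -0.94 without tumours 1 and 5, and 6 fell (8 adjusted over the list alone). mt-Co2 fell from 69.4 ± 17.0 to 3.13 ± 1.02 CPM and mt-Nd3 from 18.7 to 1.12 CPM, but 100% and 98.0% of their 50-base sequences occur elsewhere. Gm28661, a nuclear copy of mt-Co2 on chromosome 1 chosen after its values were seen, rose from 10.2 to 119 CPM. Summed over gene and nuclear copy, the log2 fold change was 0.60 (SE 0.29) for mt-Co2 and 0.25 (SE 0.29) for mt-Nd3. The falls of mt-Co2 and mt-Nd3 therefore do not show less RNA of these genes. Among the pairs compared at the end, only the sum of mt-Co1 was negative (-1.17, SE 0.36). The sum of mt-Atp6 was highest (3.38, SE 0.25).

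In glycolysis 3 of 18 members fell and 0 rose (4 fell adjusted over the list alone). Gapdh went from 239 ± 10.2 to 71.6 ± 13.3 CPM (SD; log2 fold change -1.74, SE 0.21, adjusted p = 0.00157), Pgk1 had -1.53 and Eno1 -1.36. Each shares sequence with other genes, 24.7%, 53.9% and 26.0% of the 50-base sequences. The list's median was 0.32 while its test pointed down (camera adjusted p = 0.0669), and without tumours 1 and 5 the median was -0.45 (adjusted p = 0.0103, adjusted p = 0.379 with an estimated correlation). Among 25 genes of cholesterol synthesis Fdps and Idi1, enzymes of the isoprenoid part of the pathway, fell by 2.14 and 2.47 on the log2 scale, and 0 rose (the same counts, 2 and 0, adjusted over the list alone). Their shared sequence was 26.2% and 17.7%. The list had a median of -0.27 and a camera adjusted p of 0.00524, with adjusted p = 0.577 with an estimated correlation. Of 24 interferon response and MHC class I genes Isg15 (log2 fold change -2.08, SE 0.35, adjusted p = 0.00920) and Ifi44 (-2.78) fell and 0 rose, also adjusted over the list alone. That list had a median of -0.50 (camera adjusted p = 0.000410, adjusted p = 0.363 with an estimated correlation), and 4 members fell without tumours 1 and 5.

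Over all libraries no gene of the cell cycle lists was called apart from Fen1, a flap endonuclease of DNA replication. Simulated 2-fold changes at the fitted spread were recovered in 0% of genes, so uncalled genes are not shown to be unchanged. Fen1 went from 4.07 ± 0.241 to 0.730 ± 0.514 CPM (log2 fold change -2.47, SE 0.52, adjusted p = 0.0244), and 84.2% of its exon bases lie opposite another gene. It was the 1 call among 36 E2F targets and replication genes, over all genes and adjusted over the list alone. Pcna, the sliding clamp, had a log2 fold change of -1.57 (adjusted p = 0.0876). The E2F list had a median of -0.50 (camera adjusted p = 0.000313, adjusted p = 0.706 with an estimated correlation) and the G2/M list, with 0 of 26 members called by either adjustment, -0.43 (camera adjusted p = 0.0134, adjusted p = 0.722 with an estimated correlation). Without tumours 1 and 5 the medians were -0.17 and -0.10 and neither list passed (adjusted p = 0.167 and 0.242). In that comparison Pcna fell by 1.29 and Rfc4, a subunit of the clamp loader, by 1.24. No member of the 23 cyclins, CDKs and CDK inhibitors was called by either adjustment (median -0.14, camera adjusted p = 0.204). Their smallest p belonged to Cdkn1a, the p21 inhibitor, at 27.7 and 88.5 CPM (log2 fold change 1.68, adjusted p = 0.126). Without tumours 1 and 5 the mitotic cyclin Ccnb1 fell by 1.40 (adjusted p = 0.00417) and the CDK inhibitor Cdkn2b rose by 1.27 (adjusted p = 0.0298), among 3 members higher and 1 lower (4 and 1 adjusted over the list alone).

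None of 22 tested Hedgehog pathway genes was called over all 9 libraries, by either adjustment. The median log2 fold change was 0.29 with 21 of 22 positive, while camera pointed down (adjusted p = 0.893). Boc, a Hedgehog co-receptor, had 0.74, and the Hedgehog target Gli1 had 1.01. Without tumours 1 and 5, 6 of 23 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.00446, adjusted p = 0.379 with an estimated correlation). There Boc rose by 1.03 (adjusted p = 0.0126) and Gli1 by 1.501 (adjusted p = 0.0395). Of 15 granule neuron progenitor markers none was called (median 0.12, camera adjusted p = 0.437), and 2 rose without tumours 1 and 5 (5 adjusted over the list alone, camera adjusted p = 0.110). In that comparison the astrocyte list had 8 genes lower and 0 higher, the oligodendrocyte list 7 and 2, and the Purkinje list 3 and 0. The endothelial and pericyte lists had medians of 0.05 and 0.32. Whether the Hedgehog and progenitor rises go with a smaller share of non-tumour tissue in Cdk6-/- tumours was not tested. Of 25 granule neuron differentiation markers Rbfox3, which encodes NeuN, rose from 81.3 ± 14.2 to 204 ± 55.9 CPM (SD; log2 fold change 1.33, SE 0.31, adjusted p = 0.0366), the 1 call by either adjustment. That list had a median of 1.41 (camera adjusted p = 0.442) and of -0.33 without tumours 1 and 5 (adjusted p = 0.0926), since its members were high in tumours 1 and 5.

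**Figure D2:**
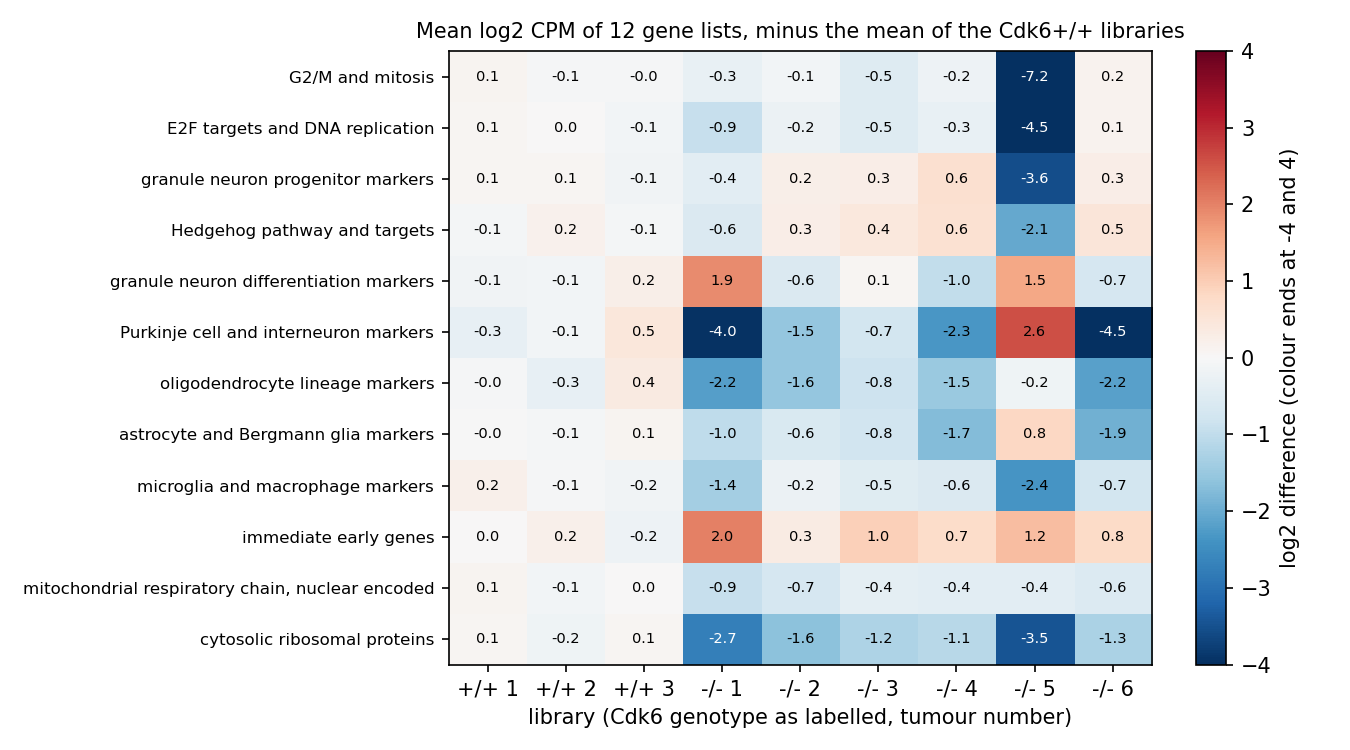
Mean log2 CPM of 12 gene lists in each library, minus the mean over the 3 Cdk6+/+ libraries, with blue for lower and red for higher. The ribosomal protein list was lower in every Cdk6-/- library, whereas the G2/M list was far below the others in tumour 5, and its median gene was there at 0.716% of its level in the other Cdk6-/- libraries.

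The lists of the unfolded protein response, p53 targets and oxysterols had no member past the test with all libraries. The 32 unfolded protein response genes had a median of 0.28 (camera adjusted p = 0.274), led by Ppp1r15a, a phosphatase subunit that ends the response, at 0.99 (adjusted p = 0.0987), which rose by 0.90 without tumours 1 and 5 (adjusted p = 0.0298). The 17 p53 targets had a median of 0.33 (camera adjusted p = 0.236), and without tumours 1 and 5 the pro-apoptotic gene Bbc3 rose by 2.004 and Sesn2 by 1.21. The 21 genes of oxysterol and sterol metabolism and transport had a median of 0.18 while camera pointed down (adjusted p = 0.472). Hsd11b2, a steroid dehydrogenase chosen after its values were seen, was at 90.4 ± 15.1 CPM (SD, n = 3) in Cdk6+/+ and 113 ± 75.8 CPM (SD, n = 6) in Cdk6-/- libraries. Without tumours 1 and 5 its mean was 158 ± 31.7 CPM (SD, n = 4), a rise of 0.81 on the log2 scale (edgeR adjusted p = 0.0352). It was the 1 rise in a list where 1 gene fell and the median was -0.02. Tumours 1 and 5 held the lowest Hsd11b2 levels of the Cdk6-/- group, 42.8 and 0.354 CPM. The rise therefore depends on leaving them out.

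Among markers of non-tumour cells, red cell and microglia genes were called most often. The red cell list had 3 of 6 members lower and 0 higher (5 lower adjusted over the list alone; median -3.32, camera adjusted p = 2.93e-05, adjusted p = 0.363 with an estimated correlation). Among the 3 are Hbb-bt and Hbb-bs, with 58.3% and 53.2% shared sequence. Of 20 microglia and macrophage markers 3 fell and 0 rose (5 fell adjusted over the list alone), including the purinergic receptor P2ry12 (log2 fold change -1.62, SE 0.27, adjusted p = 0.00964). That list had a median of -0.68 (camera adjusted p = 2.93e-05, adjusted p = 0.577 with an estimated correlation), and of -0.34 with 5 fallen without tumours 1 and 5 (camera adjusted p = 0.0103, adjusted p = 0.379 with an estimated correlation). Hopx fell by 1.40 among 15 astrocyte and Bergmann glia markers (median -0.30, 1 call by either adjustment, camera adjusted p = 0.0134, adjusted p = 0.665 with an estimated correlation), and 8 fell without tumours 1 and 5, and the water channel Aqp4 fell by 2.32. None of 17 oligodendrocyte markers was called by either adjustment (median -0.61, camera adjusted p = 0.00168, adjusted p = 0.435 with an estimated correlation), and 7 fell and 2 rose without tumours 1 and 5, and Enpp6 fell by 2.66.

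The 14 Purkinje cell and interneuron markers had a median of 0.39 with a test that pointed down (camera adjusted p = 0.0427, adjusted p = 0.706 with an estimated correlation). Without tumours 1 and 5 their median was -1.86, 3 fell, and Itpr1 fell by 1.47. No member was called among the markers of lymphocytes and neutrophils (5 tested, median -1.20, adjusted p = 0.0669), endothelium (15, 0.37, adjusted p = 0.708), pericytes, fibroblasts and meninges (19, 0.27, adjusted p = 0.633), choroid plexus and ependyma (14, 0.15 with the test down, adjusted p = 0.188) or unipolar brush cells and cerebellar nuclei (9, 0.36 with the test down, adjusted p = 0.388). Adjusted over the list alone, 1 endothelial gene, Itm2a, was lower. Immediate early genes, which respond to handling and stress within minutes, had a median of 1.00 over 15 genes (camera adjusted p = 0.00902, adjusted p = 0.479 with an estimated correlation), with 0 called over all genes and 2 higher adjusted over the list alone. Fosb, with the smallest p, was at 0.150 and 2.18 CPM (adjusted p = 0.0512), and 2 members rose without tumours 1 and 5. Of the sex-linked markers Uty passed the test (1 higher of 5, 4 adjusted over the list alone, camera adjusted p = 0.122).

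The tested genes next to Cdk6 on chromosome 5 were called more often than the rest, without adjustment for gene class. Within 10 Mb, 8 of 55 tested genes changed, 14.5% against 5.16% elsewhere (Fisher's exact test, two-sided, odds ratio 3.13, p = 0.00714). The odds ratio was 4.20 within 5 Mb (Fisher's exact p = 0.00147) and 2.69 within 20 Mb (Fisher's exact p = 0.00166). None of the 8 is protein-coding: the pseudogenes Rps4x-ps, Wdr46-ps, Gm15459 and Tubb4b-ps1, the unverified transcripts Gm43679 and Gm42490, the long noncoding Gm26825 and the unmatched Gm42426. Across all tested genes 34.2% of pseudogenes and 27.8% of unverified transcripts were called, so gene class may account for the difference. The 5 Mb window holds the same 8 calls. Gm26825 was at 65.0 and 2.82 CPM and overlaps Gm15459, whose sequence is shared to 93.8%.

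The authors' deposited table lists 761 genes at an adjusted p of at most 0.0499, 515 higher and 246 lower in Cdk6-/-, and does not include Cdk6. Of these genes 263 are pseudogenes and 84 protein-coding, and 8 ribosomal protein genes are listed as lower. edgeR tested 651 of the 761, all 651 with the same sign, and called 591. The log2 fold changes correlated across these genes (Pearson's r = 0.999), which come from the same libraries and are not independent replicates. DESeq2 run on the deposited counts called all 761.

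**Figure D3:**
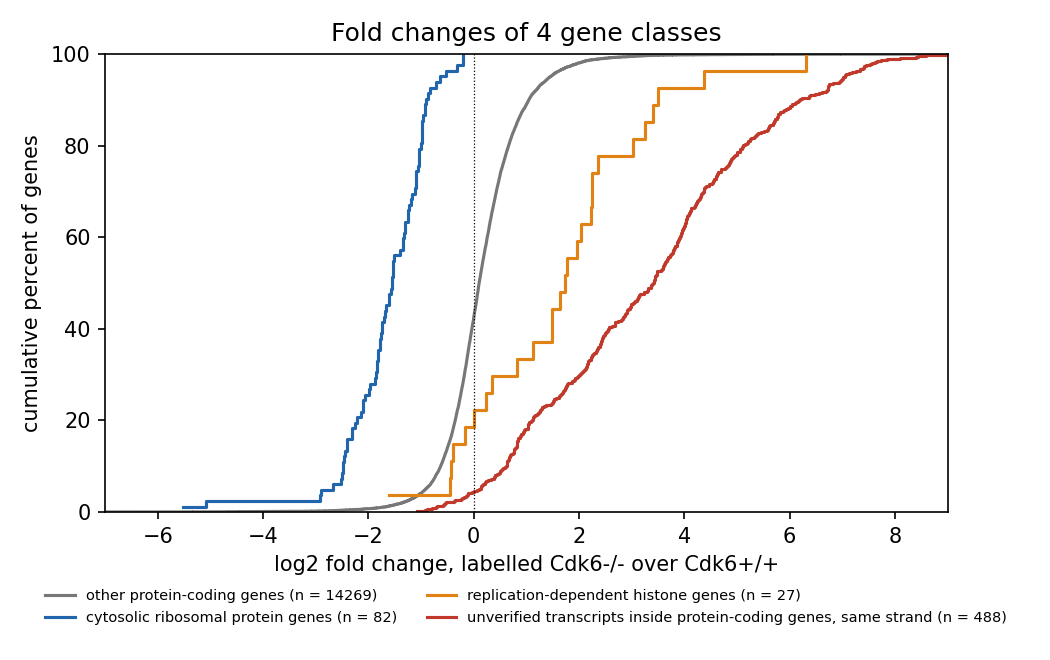
Cumulative percent of genes against the log2 fold change, labelled Cdk6-/- over Cdk6+/+, for 4 gene classes with the number of genes in the legend. The ribosomal protein genes lie to the left of 0 with a median of -1.55, and the unverified transcripts inside protein-coding genes on the same strand lie to the right with a median of 3.41.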

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

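The tests on the library of Cdk6-/- tumour 5, the comparison of strands, the lists matched on shared sequence, the ribosomal median on thinned counts and the summed histone level below were chosen only after the result was seen. Bootstrap intervals below resample the genes of a list and take them as independent. They do not measure the spread between tumours.

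Among the 6 libraries labelled Cdk6-/-, 51 values were checked for a library far from the other 5, and chance gives about 1 such value in 20. Each was found by the gap to the nearest library as a share of the whole range, given in brackets, against Dixon's critical value. The library of tumour 5 lay that far below the others for the mean log2 CPM of the lists of cyclins and CDKs (0.900), E2F targets (0.774), G2/M genes (0.911), p53 targets (0.678), granule neuron progenitor markers (0.751) and lymphocyte markers (0.633), and for Cdk6 (0.825). It lay that far above the others for the glycolysis list (0.658). Tumour 3 had the largest total, 34.5 x 1e6 counts (0.6254). The 5S RNA copy n-R5s194 had its only count of the group in tumour 1 (1.0), and Igf2bp1 had all of its counts in tumour 3 (1.0).

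The library of tumour 5 stood apart from the other 8 on the leading principal component. Its total of 24.7 x 1e6 counts lay within the range of the other Cdk6-/- libraries, which argues against sequencing depth. The median G2/M gene was at 0.716% of its level in the other 5, while the granule neuron differentiation list was at 405% and the Purkinje list at 5087%, so a candidate explanation is that this sample held mature cerebellar tissue in place of tumour. Cdk6 at 2.17 CPM cannot be told apart from a wrong label, because the counts do not separate the deleted part of the gene and a low level also goes with few dividing cells. Neither explanation was tested on other data.

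The ribosomal protein genes had a median log2 fold change of -1.55. The 14 members with under 10% shared sequence had -1.43 (bootstrap 95% interval -1.69 to -1.01), which argues against reads shared with exact annotated copies as the whole cause. Near-identical and unannotated copies were not measured. Of 10000 lists of other protein-coding genes matched on shared sequence and expression 0% reached the ribosomal median. Their own median was -0.55 (lowest list -0.77), so a part that goes with shared sequence stays open. Of 10000 lists matched on transcript length and expression 0% reached the ribosomal median (lowest list -0.38), which argues against length, and 78.4% of the median was left without tumours 1 and 5, which argues against mature tissue in those tumours. With libraries thinned to the smallest total the median was -1.54, while the number of changed genes went from 953 to 718. Thinning keeps the expected ratio between libraries, so the median could hardly move. At equal totals it stayed, which argues against the number of counts itself as the source for this list. The genotype stays open, as does anything else that goes with depth. So does a difference between the groups in library preparation or in the handling of reads with several alignments, which the labels do not give. For mt-Co2 and its near-identical copy Gm28661, 12.2% to 13.5% of the joint counts lay in the copy in Cdk6+/+ libraries. In Cdk6-/- libraries 96.6% to 97.8% did. That split goes with such a difference for this pair, and it was not measured for ribosomal protein genes.

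Unverified transcripts inside protein-coding genes on the same strand were higher in the libraries labelled Cdk6-/-, 181 of 488 with 0 lower by edgeR. Their median difference of group means of log2(CPM + 0.1) was 2.001 on thinned counts (bootstrap interval 1.90 to 2.07) and 1.99 without thinning. This measure is smaller than edgeR's fitted median of 3.41. Depth as the cause was set to give a value under 1, and the interval includes the bound of 2 set for the opposite outcome. Thinning keeps the expected ratio between libraries, so apart from effects of few counts the value could hardly move. For these transcripts, which have few counts, it does not decide on depth. A higher share on the same strand than on the opposite strand (odds ratio 3.97, Fisher's exact p = 5.41e-06) argues against genomic DNA read alike on both strands, while olfactory receptor genes at 1.80% of the level of these transcripts in tumour 5, 0.545% to 0.937% in the other Cdk6-/- and 1.11% to 2.52% in the Cdk6+/+ libraries leave some genomic DNA in tumour 5 open. Replication-dependent histone genes, whose mRNA has no poly(A) tail, had a median of 2.20 without tumours 1 and 5 (interval 0.86 to 2.604; 10 higher, 1 lower) and 1.74 over all libraries, so more RNA without a tail may be present in those libraries. Against that, the mean summed histone level was 98.2 CPM in Cdk6+/+, 103 CPM in all Cdk6-/- and 108 CPM in the Cdk6-/- libraries without tumours 1 and 5. Among ribosomal and small RNAs named in the text, Rn18s-rs5, Rn7sk and Scarna9 were higher and n-R5s194 and mt-Tp were lower. A change in splicing or transcription with the genotype was not tested.

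Of the 84 splits of the 9 tumours into 3 and 6, 1 gave as many changed genes as the real split, the real split itself, with 953 genes against at most 148 in the others. A chance assignment would give the real split this rank in 1 of 84 cases, which argues against chance as the source of the count. Every other split mixes the groups, which widens the spread within its parts and lowers its count. A technical difference that follows the groups is not excluded.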

How the results depend on the processing

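Leaving out tumours 1 and 5 together, thinning and the restriction on shared sequence were chosen only after the result was seen, and the other tests here were planned.

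The number of changed genes was 953, and 2894 by DESeq2, 3735 by limma-voom, 563 among genes with at least 1 CPM in 3 libraries, 72 with the Y-linked level as a covariate, 2643 without Cdk6-/- tumours 1 and 5 and 160 among protein-coding genes with under 10% shared sequence. The last restriction and the CPM minimum test fewer genes. The Y-linked covariate was low in every Cdk6+/+ library and high in Cdk6-/- tumours 2, 3, 4 and 5. That fit therefore separates sex from genotype poorly. For the others the cause was not tested. Leaving out each library in turn gave 207 to 1506 genes: 221, 400 and 207 without Cdk6+/+ tumour 1, 2 or 3, and 525 and 1506 without Cdk6-/- tumour 3 or 5. With the replicate block the count was 822, but tumour numbers do not pair the groups, since same-number correlations were 0.05, -0.18 and -0.25. In none of these settings did a call shared with the main test change sign. The median log2 fold change of all genes was 0.16, and 0.34 by DESeq2, which tests more genes.

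Cdk6 was lower and not called in all alternatives, with log2 fold changes from -1.12 to -0.44. The odds ratio next to Cdk6 stayed above 1 in the 5, 10 and 20 Mb windows, which overlap and were not adjusted for gene class. The number of lists past camera's threshold was 13, between 11 and 14 under the alternatives that keep the preset correlation, and 0 with an estimated correlation. The ribosomal list had a median of -1.55 in both forms of the test, with adjusted p = 0.479 with an estimated correlation and from 7.14e-34 to 1.21e-08 in its other alternatives. The estimated correlation widens the list's own null spread by construction.

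The Hedgehog list's test pointed down over all libraries and up without tumours 1 and 5, where the median was 0.57 (adjusted p = 0.00446, adjusted p = 0.379 with an estimated correlation; 0.147 to 0.961 in its other alternatives). Astrocyte, oligodendrocyte and Purkinje lists pointed down in the comparison without tumours 1 and 5, and the Hedgehog rise was not separated from the share of non-tumour tissue. Tumours 1 and 5 also had the lowest Hedgehog list means of the Cdk6-/- group. Itpr1 was at 1.44 and turned to -1.56 with the replicate block and to -1.47 without tumours 1 and 5, the latter because its level of 5527 CPM in tumour 5 was left out. It was also negative, and not called, by limma-voom (-1.43), without tumour 5 (-1.66) and with the Y-linked covariate (-2.99). Over the lists, 393 of the other comparisons with an alternative stayed on their side of the threshold, 28 lost the call and 9 gained it. Over the named genes, 1735 stayed on their side, 131 lost the call and 86 gained it. Uncalled values that changed sign are counted as staying, among them Cdon (1.12 to -0.47), Rora and Eomes and the granule neuron differentiation list (1.41 to -0.33) without tumours 1 and 5.

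Depth limits the number of calls: with libraries thinned to the smallest total 718 genes changed, against 953 at full depth. At the fitted spread, simulated 2-fold changes were recovered in 0% and 4-fold changes in 20% of 100 genes each by edgeR, so an uncalled gene is not shown to be unchanged.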

Other observations

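The genes and groupings in this part were chosen only after the result was seen.

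The genes of this paragraph were picked by hand among called genes with under 10% shared sequence and groups fully apart, which holds for 15.5% of all tested genes and for 2.38% by chance, and no list of them was tested. Eya4, a transcriptional coactivator and phosphatase, fell from 18.8 ± 2.67 to 1.38 ± 0.859 CPM (SD; edgeR adjusted p = 0.00209), and the neural transcription factor Neurod4 fell by 2.82 on the log2 scale. Chd7, a chromatin remodeller, rose from 308 ± 37.3 to 687 ± 91.9 CPM (log2 fold change 1.16, adjusted p = 0.0265), and Crebbp, Chd3 and Spen, regulators of chromatin and transcription, rose by 1.12, 1.38 and 1.62. Rec8, a meiotic cohesin subunit, rose by 3.15.

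Counts of mitochondrial genes and of their nuclear copies on chromosome 1 were compared in 7 pairs. The copy had a positive log2 fold change in all 7, from 2.51 to 4.68, while the mitochondrial gene ranged from -4.46 (mt-Co2) to 0.10 (mt-Nd4). Of the counts of mt-Co2 and Gm28661 together, 12.2% to 13.5% lay in the copy in Cdk6+/+ libraries and 96.6% to 97.8% in Cdk6-/- libraries, with a log2 fold change of the sum of 0.60 (SE 0.29). For mt-Atp6 and Gm10925 the share was 73.6% to 75.1% and 98.9% to 99.6%, and the sum had 3.38 (SE 0.25). The sum of mt-Co1 and Gm29216 had -1.17 (SE 0.36).

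Protein-coding genes with over 50% of their exon bases opposite exons of another gene were lower more often, 11 of 103, than those with none, 156 of 10040 (odds ratio 7.58, Fisher's exact p = 9.35e-07), but those with over 0 to 10% were lower less often, 26 of 2850 (odds ratio 0.58, Fisher's exact p = 0.00898). The ribosomal RNA gene Rn18s-rs5 was at 1461 and 8804 CPM (log2 fold change 2.59, adjusted p = 0.0225) and the small nuclear RNA Rn7sk at 38.5 and 215 CPM (2.48, adjusted p = 0.00964).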
